A study of Mus musculus with 24 samples.

How the data were processed

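The data were 24 two-colour arrays of a focused mouse design (Sterolgene V1), 6 in each of 4 genotypes. Per the labels, the treated liver RNA was labelled with Cy5 and the pool of 6 vehicle livers of the same genotype with Cy3 on every array, so no dyes were swapped and a dye bias of single probes is not cancelled in a response. For WT replicate 1 the treatment tag of the second channel names phenobarbital, while its source name gives the untreated WT pool and its protocol vehicle; it was read as the pool. An age of 9 to 12 weeks is given for the deficient mice only. Per the labels, a commercial spike-in scorecard was added to the treated channel and firefly luciferase to the pool channel, so equal amounts of the spike-ins in both channels are not certain.

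Per the file headers, each array's file gives the mean and median pixel intensity of each spot in both channels, the median and SD of the local background intensity, the percent of saturated pixels and a flag per spot; the signal-to-noise score per the file headers was not used. The scanner, the software and the reasons for the flags are not given in the sources used here. The deposited value table holds log2 ratios, as a comparison with the scanner values showed: its columns correlated with the unnormalized log2 Cy5/Cy3 ratios at r of 0.78 to 0.99 (median 0.95), which also gave the direction. How the authors centred these values is not given. The array medians ran from -0.43 to 2.95, and the table was used as an alternative. These medians largely followed those of the probes relative to the calibration spike-ins. They were 2.65 and 2.95 against 2.68 and 2.82 in CAR/PXR-deficient replicates 1 and 2, but 0.06 against -0.36 in WT replicate 6. The table and spike-in centring may thus share their scaling and should not be read as separate lines of evidence. Each array has 578 spots, of which 360 are the 120 mouse probes in 3 copies and the rest are controls. Of the 8640 mouse probe spots over all arrays, 5296 were unflagged, 3258 carried the flag -50 and 86 the flag -100; all 86 had saturated pixels. WT replicate 6 had 0 percent of its probe spots flagged, against up to 66.4 percent on other arrays.

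Analyses used R 4.3.3 and limma 3.58.1, with figures from Python 3.11.15 and matplotlib 3.10.9. Background was corrected with normexp (offset 50) on the mean intensities, each array was normalized by loess over its unflagged probe spots with control spots at weight 0, flagged spots were left out and the remaining copies of a probe were averaged. A probe was tested if, on at least 12 of the 24 arrays, at least 2 of its spots lay above the local background by 2 SD of it in either channel; 80 probes passed. All samples entered 1 group-means fit (lmFit and eBayes, constant prior), with a shared estimate of the spread. The 4 responses were tested against 0 and the 6 differences between genotypes as contrasts, and p-values were adjusted by the Benjamini-Hochberg method within each comparison at 0.05. All statements of adjusted p in the text come from this limma fit unless another test is named. Within each group all pairs of arrays were compared, 60 in total: the variance of the difference between PXR-deficient replicates 1 and 2 was 0.96 times that expected from replicate spots, while the other pairs gave 2.08 to 62.7. The mean of these 2 arrays was used, written as replicates 1-2. The plan had been to count all 24 arrays; this change was made after the data were seen, and the count with 24 arrays is among the alternatives.

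The rule fixed before the data were examined named up to 10 highest and 10 lowest genes per comparison and a set of named genes, and 12 gene lists, cell type markers and the receptor genes Nr1i3 and Nr1i2 were planned. The files and tables used here do not pair the probes with genes, so none of these could be tested, the genotype labels could not be checked on the receptors' own transcripts, and the rule had no gene to name. The same rule said that probes without a gene name would not be named. After the files were seen this was changed: the 2 highest and 2 lowest probes past the threshold in each comparison are given by probe number, and this limit was set after their values were seen. Levels per channel came from the loess-normalized values after Aquantile normalization between arrays, with only the spots of flag -100 left out. Alternatives to the background correction, normalization, filters, weights, thresholds and samples were run, and their effect is given after the results.

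The fit was tested on simulated data with the measured missing values, independent samples and a single spread per probe, pooled over the groups. Unequal spreads between groups and alike arrays were not simulated, so recovery in the measured data may differ. For the 80 probes, changes of 1 on the log2 scale were recovered in 85.7 to 97.8 percent of cases over the 10 comparisons, and changes of 0.5 in 35.0 to 81.2 percent. In a test of the intensity steps, the treated channel of 10 probes spread over the brightness range was doubled in WT; the normalized values of the response in WT rose by a median of 0.71 in place of 1, and by 0.89 with median centring. With 10 probes adjacent in brightness the medians were 0.58 and 0.86. Loess on this small array thus takes up part of a change.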

Results

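The study measured liver transcripts of male C57BL/6J mice 12 h after an intraperitoneal injection of 100 mg/kg phenobarbital, a barbiturate long used as an inducer of hepatic drug-metabolizing enzymes. Its title asks which genes of drug metabolism and cholesterol homeostasis are regulated by CAR and PXR, 2 nuclear receptors that sense foreign compounds. There were 4 groups of 6 arrays: wild-type (WT) mice and mice deficient in CAR, in PXR or in both receptors (CAR/PXR-deficient). On each array the Cy5 channel held the RNA of phenobarbital-treated liver and the Cy3 channel held a pool of 6 livers of the same genotype from mice given vehicle (5% DMSO in corn oil). A positive log2 ratio therefore means a higher level after phenobarbital. The labels do not state that the replicates of a group are separate mice, so p-values measure only the spread between these samples. The array is a focused design with 120 mouse probes, each spotted 3 times, and 80 probes were bright enough to be tested. The files do not pair probe numbers with genes, so the probes are given by number and no gene, pathway or cell type can be named. The number of probes with a usable value ranged from 45 to 120 per array (median 81). The median number of probes above background was 56 on WT arrays, 76.5 on CAR-deficient, 82.5 on PXR-deficient and 93 on CAR/PXR-deficient arrays. The number of arrays limits the precision of every mean. PXR-deficient replicates 1 and 2 differed by less than the noise of replicate spots and were counted as 1 sample, which left 23 samples.

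Phenobarbital raised 12 probes and lowered 8 of the 80 tested in WT liver. The response was dominated by Mm038 and Mm039. Mm038 rose 8.05-fold (log2 ratio 3.01 ± 0.75, SD, n = 6; SE 0.29, adjusted p = 1.36e-06) and Mm039 rose 6.33-fold (2.66 ± 0.67, n = 6; SE 0.25, adjusted p = 9.17e-07), each in 6 of 6 samples. In the vehicle pool Mm038 and Mm039 were above background on 1 of 6 arrays each, so these folds are set by a reference signal near background. In all, 4 probes rose by more than 2-fold and the smallest rise that passed was 0.38 on the log2 scale. The decreases were smaller. Mm046 fell 1.51-fold (log2 ratio -0.59 ± 0.29, n = 6; SE 0.12, adjusted p = 0.000810) in 6 of 6 samples. Mm014 had a log2 ratio of -0.63 ± 0.49 (n = 5; SE 0.18, adjusted p = 0.0106), with 1 of the 5 samples near 0 at -0.0011. Its treated channel was above background on 2 of 6 arrays, so the size of its fall is uncertain. Each response was tested with limma as a group mean against 0, which leaves out the spread between control animals because 1 pool per genotype served as the reference. The call of Mm014 was lost without WT replicate 5 (adjusted p = 0.0556) and without WT replicate 6 (0.0877), with no background correction (0.0972), with array quality weights (0.0548), in the authors' value table (0.453) and in that table after median centring (0.259). That of Mm046 was lost with median centring (0.220), in the authors' value table (0.369) and in that table after median centring (0.194). The count of 20 fell to 12 with the WT arrays fitted alone and to 3 in the authors' value table (3 risen, 0 fallen). With spike-in centring 5 rose and 10 fell.

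No probe passed the threshold in CAR-deficient liver: limma called 0 of 78 probes, with 12 at an unadjusted p under 0.05 and a lowest adjusted p of 0.155. The responses were also small, with a median absolute log2 ratio of 0.11 over the tested probes, against 0.20 in WT. Mm039 had a log2 ratio of 0.07 ± 0.10 in the 2 samples that measured it. Mm038 gave no usable ratio here, since all its spots were flagged. It was also not well above background in either channel on any of the 6 arrays. In the treated channel alone, Mm038 was at least 15.5-fold higher in WT than in CAR-deficient liver. It was at least 14.5-fold higher in PXR-deficient than in CAR-deficient liver. An exact two-sided permutation test on the bounded levels gave p = 0.00216 for each, the smallest it can give. The groups had been chosen as above background on all arrays and on no array, which nearly fixed that outcome, so it decides nothing. These bounds set the mean of the brighter group against the lowest signal counted as above background on each array, per channel after loess and Aquantile normalization, and differ between arrays in brightness. The count of 0 depends on the fit and the normalization: it became 18 when the CAR-deficient arrays were fitted alone, 20 with array quality weights and 16 with scale normalization between arrays; it was 54 with centring on calibration spike-ins, 35 in the authors' value table and 11 in that table after median centring.

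**Figure D1:**
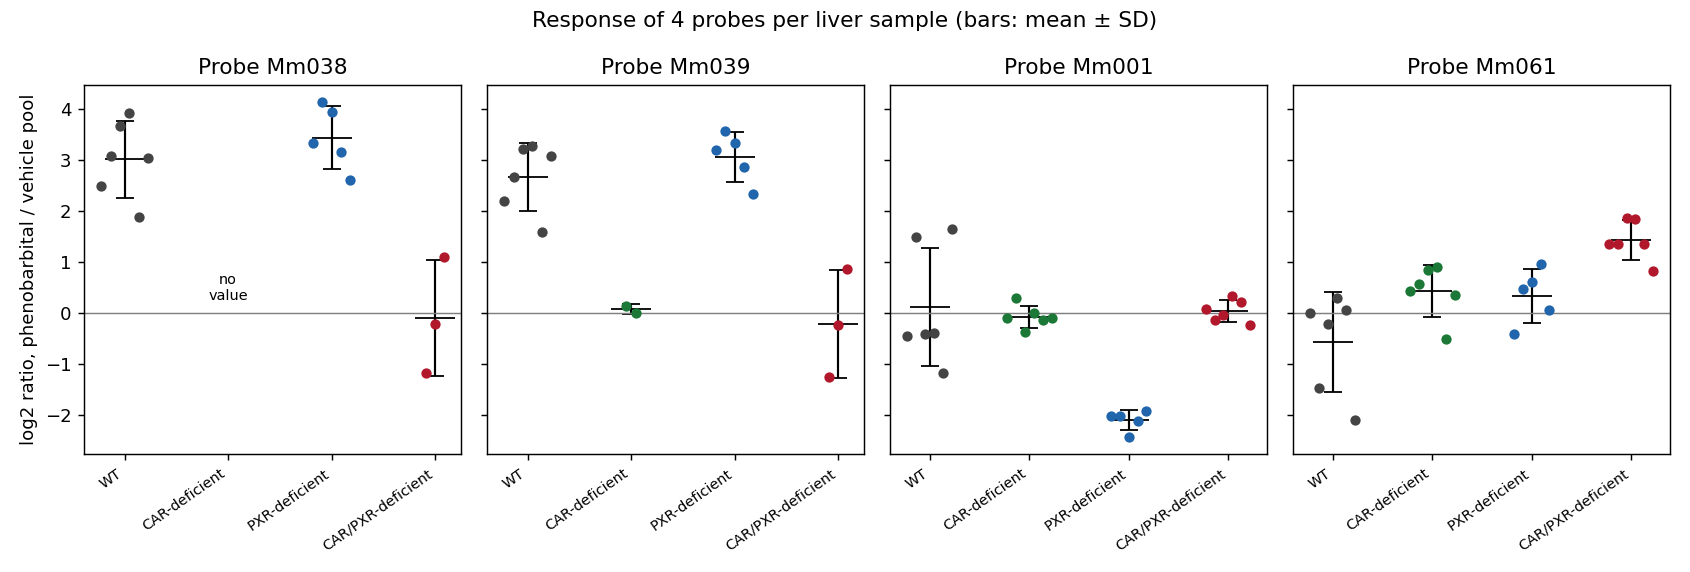
Log2 ratios of phenobarbital-treated liver over the vehicle pool (vertical axis, log2 units) for probes Mm038, Mm039, Mm001 and Mm061 in the 4 genotypes (horizontal axis); points are samples, horizontal marks the means and error bars 1 SD. Mm038 and Mm039 were high in WT and PXR-deficient liver, Mm001 was low in PXR-deficient liver (mean -2.10) and Mm061 was high in CAR/PXR-deficient liver (mean 1.43).

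In PXR-deficient liver phenobarbital raised 16 probes and lowered 10 of the 80 tested. Mm038 and Mm039 led again. Mm038 rose 10.8-fold (log2 ratio 3.43 ± 0.62, n = 5; SE 0.31, adjusted p = 4.01e-07) and Mm039 rose 8.30-fold (3.05 ± 0.48, n = 5; SE 0.27, adjusted p = 2.41e-07), each in 5 of 5 samples. The pool channel was above background for Mm038 on 2 of the 6 arrays and for Mm039 on 3 of the 6. Mm001 had a ratio lower than 1 by 4.30-fold (log2 ratio -2.10 ± 0.20, n = 5, SE 0.26, adjusted p = 5.08e-07) in 5 of 5 samples. All these ratios share 1 pool, in which Mm001 had a normalized log2 level of 11.46, against 9.66 to 9.96 in the other genotypes' pools. Its treated-channel level was 9.36, against 9.58 to 10.07. A fall after phenobarbital and a pool that stood apart therefore cannot be told apart. Mm024 had a log2 ratio of -1.05 ± 0.24 in the 3 samples that measured it (SE 0.28, adjusted p = 0.0201). Its pool level was also higher than in the other genotypes, at 9.47 against 7.92 to 8.30. Its treated channel was above background on 2 of 6 arrays, so the size of its fall is uncertain. In all, 6 probes rose and 4 fell by more than 2-fold. The count of 26 fell to 16 without replicate 3, to 15 without replicate 4, and to 15 when replicates 3 and 4, and WT replicates 2 and 6, were also counted as 1 sample each. The call of Mm024 did not pass without replicates 1-2, without replicate 3 or without replicate 4 (adjusted p = 0.0521, 0.0607 and 0.119), with print-tip loess (0.0596), in the authors' value table (0.266) or with 3 alike pairs counted once (0.0773). The split was 23 risen and 2 fallen with spike-in centring and 11 and 1 in the authors' value table.

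In CAR/PXR-deficient liver 13 probes rose and 14 fell of the 80 tested. The probes that rose most were not those that rose most in WT, while Mm014 had the lowest log2 ratio among the probes that fell in both. Mm061 rose 2.69-fold (log2 ratio 1.43 ± 0.38, n = 6; SE 0.25, adjusted p = 0.000208) in 6 of 6 samples, and Mm054 rose 2.12-fold (1.09 ± 0.88, n = 6; SE 0.21, adjusted p = 0.000500) in 5 of 6. Mm014 fell 1.98-fold (log2 ratio -0.99 ± 0.57, n = 6; SE 0.16, adjusted p = 0.000208) in 5 of 6 samples. Mm133 fell 1.72-fold (-0.79 ± 0.40, n = 6; SE 0.12, adjusted p = 0.000107) in 6 of 6. Mm038 and Mm039 had log2 ratios of -0.10 ± 1.14 and -0.22 ± 1.06 in the 3 samples that measured them. The direction of the falls depends on how arrays were centred: with centring on the calibration spike-ins Mm014 and Mm133 had log2 ratios of 0.09 and 0.42, and log2 ratios of 0.36 and 0.80 in the authors' value table, the latter at an adjusted p of 0.00662. Replicates 1 and 2 weigh most on this change of sign. Their probe medians exceeded those of the calibration spike-ins by 2.68 and 2.82, against 0.54 to 1.06 on the other arrays. Their medians in the authors' value table were 2.65 and 2.95. The sign without these 2 arrays was not tested. The count was 13 when this group was fitted alone, and with spike-in centring and in the authors' value table alike 74 probes rose and 0 fell.

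**Figure D2:**
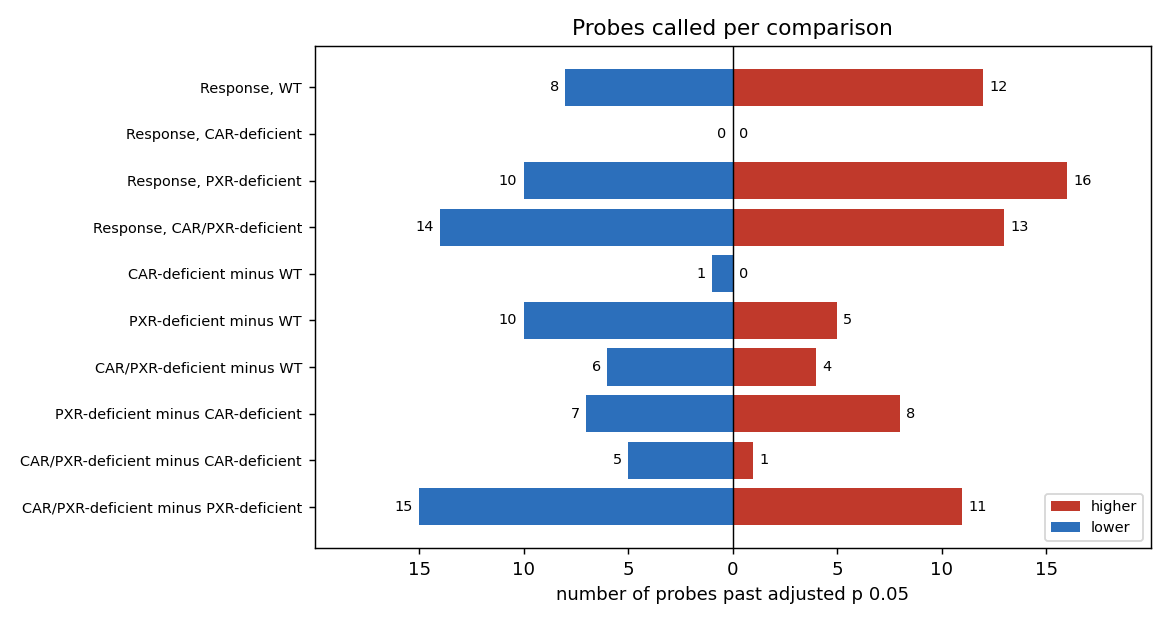
Number of probes past an adjusted p of 0.05 (horizontal axis, probes; higher to the right, lower to the left) in the 4 responses to phenobarbital and the 6 differences between genotypes (vertical axis). The CAR-deficient response had 0 calls and the CAR/PXR-deficient response had 13 higher and 14 lower.

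Whether loss of a receptor changed the response was tested as the difference of log2 ratios between genotypes, in which a dye effect common to all arrays cancels. CAR-deficient and WT liver differed in 1 probe of 78, with 21 at an unadjusted p under 0.05; 7 of 100 splits of these samples, the real one included, gave as many. This was Mm039, whose log2 ratio was lower without CAR (difference -2.59, SE 0.49, adjusted p = 0.00650; 0.07 in 2 samples against 2.66 in 6). This call did not pass without CAR-deficient replicate 5 or 6 (adjusted p = 0.0922 and 0.111), with no background correction, in the authors' value table or on the upper arrays alone. The count rose to 12 without WT replicate 5 and to 5 without WT replicate 1. It was 0 without CAR-deficient replicate 5 or 6, and 2 without WT replicate 3 or 6 or without CAR-deficient replicate 1. With spike-in centring 49 probes were higher and 1 lower, and 16 were higher and 0 lower in the authors' value table.

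CAR/PXR-deficient and WT liver differed in 10 probes, 4 higher and 6 lower. Mm038 was lower by a log2 difference of -3.11 (SE 0.50, adjusted p = 0.000347; -0.10 in 3 samples against 3.01 in 6) and Mm039 by -2.88 (SE 0.43, adjusted p = 0.000193; -0.22 in 3 samples against 2.66 in 6). The sizes of both are uncertain: each probe was above background in the WT pool on 1 of 6 arrays and in CAR/PXR-deficient liver on 2 of 6 arrays in the treated channel and 3 of 6 in the pool. Neither passed in the authors' value table (adjusted p = 0.102 for Mm038 and 0.297 for Mm039). Mm061 was higher by 2.004 (SE 0.35, adjusted p = 0.000193), with 1.43 ± 0.38 against -0.58 ± 0.98 (n = 6 each). In WT it was -1.47 and -2.11 in replicates 2 and 6, which were nearly alike, and -0.22 to 0.30 in the others. The low WT mean thus rests on this pair. The call still passed with alike pairs counted once. Mm062 was higher by 0.87 (SE 0.14, adjusted p = 0.000148), with 0.40 ± 0.31 against -0.47 ± 0.13 (n = 6 each). Its treated-channel levels were alike (normalized log2, 11.17 against 11.29), while the single pools differed (10.77 against 11.75). For Mm061 the treated-channel levels were 11.35 against 10.48 and the pools 9.93 against 11.06. For both probes a change of response and a difference between pools cannot be told apart. The count fell to 5 without CAR/PXR-deficient replicate 1, to 6 without replicate 2 and to 6 without replicate 3, and it was 4 when only these 2 groups were fitted. The split turned to 72 higher and 2 lower with spike-in centring and to 60 higher and 1 lower in the authors' value table.

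PXR-deficient and WT liver differed in 15 probes, 5 higher and 10 lower. Mm051 was higher by 1.02 (SE 0.22, adjusted p = 0.00291), with 1.44 ± 0.21 (n = 5) against 0.43 ± 0.70 (n = 6), and Mm050 by 0.71 (SE 0.21, adjusted p = 0.0173), with 1.46 ± 0.42 (n = 5) against 0.75 ± 0.39 (n = 6). In WT Mm051 ran from -0.41 to 1.12, with -0.07 and -0.41 in the nearly alike replicates 2 and 6 and -0.11 in replicate 5. Mm001 was lower by -2.21 (SE 0.35, adjusted p = 8.54e-05), with -2.10 ± 0.20 (n = 5) against 0.11 ± 1.16 (n = 6). In WT Mm001 was 1.48 and 1.64 in replicates 2 and 6 and -1.18 to -0.41 in the others, so the mean of 0.11 matched no sample. The size of this difference is uncertain, and the single pools differed too (11.46 against 9.96). Mm024 was lower by -1.90 (SE 0.44, adjusted p = 0.0173) on 3 samples against 2, WT replicates 1 and 6. Its size is uncertain, with the WT pool above background on 1 of 6 arrays and the PXR-deficient treated channel on 2 of 6. The count was 9 without WT replicate 6, 9 without PXR-deficient replicate 4, 4 when only these 2 groups were fitted and 6 with median centring. Mm050 did not pass without PXR-deficient replicates 1-2 (adjusted p = 0.0556), nor Mm024 without WT replicate 6 or PXR-deficient replicate 4 (adjusted p = 0.138 and 0.0528), with spike-in centring (0.0508), in the authors' value table (-0.94, adjusted p = 0.372) or with replicate number as a block (0.264). Mm051 and Mm050 did not pass with scale normalization (adjusted p = 0.0633 and 0.165) or with only these 2 groups fitted (0.0540 and 0.0728), nor did Mm050 with median centring (0.101). The split turned to 27 higher and 1 lower with spike-in centring and to 7 higher and 1 lower in the authors' value table.

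The deficient groups were also set against each other. PXR-deficient and CAR-deficient liver differed in 15 of 78 probes, 8 higher and 7 lower in PXR-deficient liver. Mm039 was higher by 2.98 (SE 0.50, adjusted p = 0.000468; 3.05 in 5 samples against 0.07 in 2). Mm052 was higher by 1.53 (SE 0.38, adjusted p = 0.0111) on 2 PXR-deficient samples, because saturated spots were flagged in the others; with those spots kept the difference was 1.40. Its size is uncertain, as the probe lay near saturation. Without PXR-deficient replicates 1-2 its adjusted p was 0.112. Mm001 was lower by -2.03 (SE 0.35, adjusted p = 0.000291) and Mm059 by -1.09 (SE 0.30, adjusted p = 0.0111), the latter with -1.05 ± 0.31 (n = 5) against 0.05 ± 0.27 (n = 6). Mm059 did not pass with print-tip loess (adjusted p = 0.0605) or spike-in centring (0.0668), and neither Mm059 nor Mm052 did in the authors' value table (0.110 and 0.487). The split was 4 higher and 1 lower with spike-in centring and 1 higher and 2 lower in the authors' value table.

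CAR/PXR-deficient and PXR-deficient liver differed in 26 of 80 probes, 11 higher and 15 lower in CAR/PXR-deficient liver. Mm038 and Mm039 were lower by -3.53 (SE 0.51, adjusted p = 9.58e-05) and -3.27 (SE 0.44, adjusted p = 7.97e-05). Mm001 was higher by 2.13 (SE 0.35, adjusted p = 7.97e-05), with 0.03 ± 0.22 (n = 6) against -2.10 ± 0.20 (n = 5). Mm024 was higher by 1.76 (SE 0.37, adjusted p = 0.00498), with 0.71 ± 0.59 (n = 4) against -1.05 ± 0.24 (n = 3). Mm038, Mm039 and Mm024 were above background on at most 3 of 6 arrays in at least 1 channel of each group, so the sizes of these 3 differences are uncertain. The split turned to 30 higher and 4 lower with spike-in centring and to 34 higher and 3 lower in the authors' value table.

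CAR/PXR-deficient and CAR-deficient liver differed in 6 of 78 probes, 1 higher and 5 lower. Mm062 was higher by 0.50 (SE 0.14), Mm014 lower by -0.90 (SE 0.23) and Mm012 lower by -0.82 (SE 0.19), each at an adjusted p of 0.0312. Mm014 had -0.99 ± 0.57 (n = 6) against -0.09 ± 0.22 (n = 6) and Mm012 -0.51 ± 0.41 (n = 6) against 0.31 ± 0.26 (n = 5). The count was 0 when CAR/PXR-deficient replicate 1 or 5, or CAR-deficient replicate 2, 3, 5 or 6, was left out, and 1 without CAR-deficient replicate 1. It was also 0 with median centring and with the stricter filter on dim probes, and Mm012 had a log2 difference of 0.33 in the authors' value table. Mm014 and Mm012 did not pass with spike-in centring (adjusted p = 0.362 and 0.461) or in the authors' value table (0.675 and 0.472). Mm062 and Mm012 did not pass in that table after median centring (0.0603 and 0.123), nor did Mm062 without CAR/PXR-deficient replicate 3 (0.0505), Mm062 and Mm014 without CAR-deficient replicate 1 (0.0506 and 0.0534), or Mm062 with a fold of at least 1.5 as a condition. The split turned to 8 higher and 0 lower with spike-in centring and to 17 higher and 0 lower in the authors' value table.

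The spot coordinates in the files place each array at 1 of 2 positions, here called upper (larger vertical coordinates) and lower, which the fit left out. In the deficient groups odd-numbered arrays were upper and the next number was lower. The variance of the difference within such pairs was 0.96 to 28.1 times that expected from replicate spots. Whether a pair shared a slide is not given. Apart from PXR-deficient replicates 1 and 2 the fit counted these arrays as independent, so p-values could be too small if pairs are related. With position as a term the 6 differences had counts of 1, 16, 10, 15, 7 and 28, in the order CAR-deficient, PXR-deficient and CAR/PXR-deficient minus WT, then PXR-deficient and CAR/PXR-deficient minus CAR-deficient and CAR/PXR-deficient minus PXR-deficient. The 14 upper arrays alone gave 0, 2, 5, 5, 0 and 13, and the 10 lower arrays alone gave 7, 14, 4, 8, 0 and 12. Among the lower arrays WT had 1 array, which was assumed to vary like the other groups. Besides the 3 probes named for CAR/PXR-deficient minus CAR-deficient, which passed in neither part, the upper arrays alone lost the calls of Mm024 in the PXR-deficient response, Mm039 in CAR-deficient minus WT, Mm051, Mm050 and Mm024 in PXR-deficient minus WT, and Mm059. The lower arrays alone lost those of Mm014 and Mm046 in WT, of Mm054, Mm014 and Mm133 in CAR/PXR-deficient liver, of Mm050, of Mm062, Mm038 and Mm039 in CAR/PXR-deficient minus WT, and of Mm059.

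The probes that responded in WT were followed through the other genotypes. Of the 12 that rose in WT, 11 had a value in CAR-deficient liver, where 0 passed the threshold. There 10 had a lower log2 ratio than in WT and 1 differed from WT in the test of the difference. Lower values elsewhere are likely for probes chosen as risen in WT, so the count of 10 decides nothing. In PXR-deficient liver 7 of the 12 rose, 1 fell, and 6 differed from WT in the test of the difference. In CAR/PXR-deficient liver 1 of the 12 rose and 4 differed from WT. Of the 8 that fell in WT, 0 passed in CAR-deficient liver and 0 differed from WT there. In PXR-deficient liver 1 of the 8 fell and 0 differed from WT. In CAR/PXR-deficient liver 2 of the 8 fell, 1 rose, and 2 differed from WT. The 7 probes that rose in both WT and PXR-deficient liver compare with 2.4 for independent lists of 12 and 16 among 80. A one-sided Fisher's exact test gave p = 0.00159, adjusted p = 0.00955 over the 6 overlaps that could be tested. The 2 groups had different arrays and different pools. The test treats probes as independent, while probes with neighbouring numbers responded alike in both groups, so this p-value may be too small. WT and CAR/PXR-deficient liver shared 1 risen probe, against 1.95 for independent lists (adjusted p = 0.900). The fallen lists of WT and PXR-deficient liver shared 1 probe, against 1 for independent lists, and those of WT and CAR/PXR-deficient liver 2, against 1.4 (adjusted p = 0.900 for each). PXR-deficient and CAR/PXR-deficient liver shared 2 risen and 2 fallen probes, against 2.6 and 1.75 (adjusted p = 0.900 for each). A dye bias of single probes would act alike in all 4 responses.

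Across the probes, which are not independent replicates, the mean log2 ratios of WT and PXR-deficient liver had a Pearson r of 0.68 and a Spearman rho of 0.33. For WT and CAR-deficient liver they were 0.26 and 0.29, for WT and CAR/PXR-deficient liver 0.13 and 0.26, for CAR-deficient and PXR-deficient liver 0.38 and 0.43, for CAR-deficient and CAR/PXR-deficient liver 0.41 and 0.39, and for PXR-deficient and CAR/PXR-deficient liver 0.06 and 0.14. The order of the pairs depends on Mm038 and Mm039. Without these 2 probes r was 0.34, 0.30, 0.29, 0.42, 0.41 and 0.15 in the same order, so the higher r of WT and PXR-deficient liver rested on them.

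The levels per channel are given for probes whose ratios differed between genotypes. Mm038 had a treated-channel level of 12.42 ± 0.49 in WT and 12.32 ± 0.21 in PXR-deficient liver, and of 8.38 ± 0.60 in CAR/PXR-deficient liver (normalized log2 intensity, SD). Mm001 had treated-channel levels from 9.36 ± 0.17 in PXR-deficient to 10.07 ± 1.41 in WT liver. Its level in the vehicle pool was 11.46 ± 0.28 in PXR-deficient liver, against 9.66 ± 0.16, 9.87 ± 0.21 and 9.96 ± 0.46 in CAR-deficient, CAR/PXR-deficient and WT liver. For 3 other named probes the levels are in the order WT, CAR-deficient, PXR-deficient and CAR/PXR-deficient liver. Mm062 had treated-channel levels of 11.29 ± 0.19, 11.37 ± 0.48, 10.98 ± 0.33 and 11.17 ± 0.24, with pool levels of 11.75 ± 0.31, 11.47 ± 0.46, 11.20 ± 0.15 and 10.77 ± 0.18. Mm014 had treated-channel levels of 9.24 ± 0.46, 9.66 ± 0.27, 9.05 ± 0.21 and 9.43 ± 0.47, with pool levels of 9.80 ± 0.13, 9.75 ± 0.22, 9.37 ± 0.49 and 10.42 ± 0.17. Mm061 had treated-channel levels of 10.48 ± 1.01, 11.35 ± 0.67, 10.40 ± 0.55 and 11.35 ± 0.31, with pool levels of 11.06 ± 0.24, 10.93 ± 0.31, 10.08 ± 0.32 and 9.93 ± 0.17. These levels were not tested. Each pool was a single mixture, so these SDs are between arrays, not animals. Where the pools differed between genotypes, as for Mm001, Mm062, Mm014 and Mm061, a change of response and a difference between pools cannot be told apart.

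**Figure D3:**
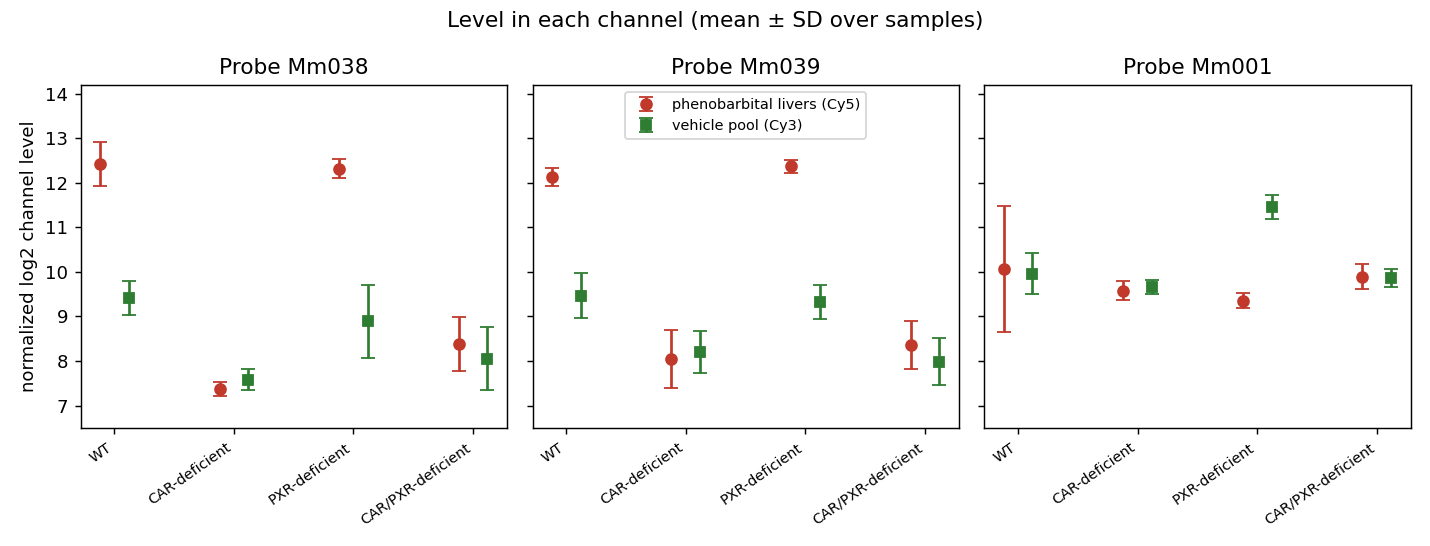
Normalized log2 intensity (vertical axis) of probes Mm038, Mm039 and Mm001 in the phenobarbital-treated livers (Cy5, circles) and the vehicle pools (Cy3, squares) of the 4 genotypes (horizontal axis); markers are means over samples and error bars 1 SD. For Mm001 the pool of PXR-deficient liver, at 11.46, lay above the 3 other pools.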

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

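The tests of repeated RNA, brightness, dye bias, the role of CAR, the loess curve and the split of the PXR-deficient set into risen and fallen probes were chosen after the results were seen; those of repeated scans, of the vehicle pool over the whole set and of other splits were written before. The loess test replaced one on the calls alone, and its limits for the risen and the fallen part were set after its values were known.

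Each of the 6 tests of a difference between genotypes called probes: 1 for CAR-deficient minus WT, 15 for PXR-deficient minus WT, 10 for CAR/PXR-deficient minus WT, 15 for PXR-deficient minus CAR-deficient, 6 for CAR/PXR-deficient minus CAR-deficient and 26 for CAR/PXR-deficient minus PXR-deficient. Of 100 splits of the same samples, the real one included, 7 gave as many calls for CAR-deficient minus WT (highest other 2), so chance cannot be excluded there. For PXR-deficient minus WT 3 did (share 0.035 after adjustment over the 7 split tests), and another split gave 18, more than the real 15. For the other 4 differences only the real split, 1 of 100, reached its count (adjusted share 0.014), with highest others of 6, 11, 4 and 18 in the order above. By these shares such counts were rare among shuffled sample labels for these 5 differences under the settings used. The splits cannot exclude chance in a pool or an animal. Each genotype had 1 pool, and the samples may not be separate mice. Alike pairs other than PXR-deficient replicates 1 and 2 were also shuffled as separate samples. The count of CAR/PXR-deficient minus CAR-deficient was 0 without any 1 of 6 samples and with median centring.

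Mm038 and Mm039 rose in WT and PXR-deficient liver and differed from the groups without CAR. The log2 differences were -2.59 for Mm039 in CAR-deficient minus WT, -3.11 and -2.88 for Mm038 and Mm039 in CAR/PXR-deficient minus WT, 2.98 for Mm039 in PXR-deficient minus CAR-deficient, and -3.53 and -3.27 for both in CAR/PXR-deficient minus PXR-deficient liver; their sizes are uncertain, as the pools and the groups without CAR lay near background. Dimmer arrays in the groups without CAR are argued against, since their medians of probes above background in the treated channel, 67 in CAR-deficient and 84.5 in CAR/PXR-deficient liver, exceeded that of WT (53, by at least 14), where the probes rose; the median was 79 in PXR-deficient liver, above that of CAR-deficient but below that of CAR/PXR-deficient liver. The mean of both probes was lower by -2.99 in CAR/PXR-deficient than in WT liver under the same dyes. This restates the pattern and is no separate test of a dye bias. A bias alike on all arrays would cancel in such a difference. The mean of Mm039 over both groups without CAR was -0.072, which restates the pattern and decides nothing, so that loss of CAR removes the rise stays an open hypothesis, as does a wrong genotype label, since the receptors' transcripts could not be checked.

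A set of 13 probes stood apart in PXR-deficient liver, 6 risen and 7 fallen, defined as past the threshold in that response and different from at least 2 other groups in the same direction. For the risen probes, the loess curve on arrays with few measured probes is argued against only for their differences from the groups without CAR. With median centring 100 percent of them met this definition, which differences from those 2 groups alone can fulfil. For their differences from WT the loess curve stays open, since 1 of them, not 3, differed from WT there. It also stays open for the fallen probes (57.1 percent) and the whole set (76.9 percent). An unusual vehicle pool of PXR-deficient livers would place the deviation in the pool channel; the median share there was 31.8 percent over the whole set, -15.4 percent for the risen probes and 50.3 percent for the fallen. This argues against the pool as the whole cause for the risen probes, of which 3, Mm039 among them, did not pass the test of a difference from WT; the other 3 had a median share of 7.70 percent and a highest of 36.4 percent. For the fallen probes the pool and the treatment cannot be told apart, since shares ran from -7.33 to 79.4 percent, and each genotype had 1 pool, which may differ by mixing, by single animals or by the genotype's own baseline.

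PXR-deficient replicates 1 and 2, and WT replicates 2 and 6, were nearly alike, with r of 0.98 and 0.99 between their log2 ratios. A single array scanned again is argued against, since deviations of single spots from their probe's mean correlated at 0.0141 and 0.0559, against a range of -0.22 to 0.25 over all 60 pairs. The same pair of RNA extracts on both arrays remains a candidate explanation for PXR-deficient replicates 1 and 2, whose variance ratio was 0.96. For WT replicates 2 and 6 the ratio was 2.82, and noise between arrays could account for it, so repeated and separate extracts cannot be told apart. With medians over the probes in place of means their ratio was 0.80, against 0.67 for PXR-deficient replicates 1 and 2. The main fit counted WT replicates 2 and 6 as separate samples. Other pairs had lower ratios by means: 2.08 for CAR/PXR-deficient replicates 1 and 2, 2.27 for PXR-deficient replicates 3 and 4 and 2.64 for CAR-deficient replicates 2 and 6. By medians these pairs had higher ratios than WT replicates 2 and 6, at 2.81, 1.26 and 2.44 in the same order. Of these only PXR-deficient replicates 3 and 4 were counted once in an alternative. No biological explanation was tested.

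Other probes differed between genotypes by the same test. PXR-deficient minus WT gave 1.02 for Mm051, 0.71 for Mm050, -2.21 for Mm001 and -1.90 for Mm024. CAR/PXR-deficient minus WT gave 2.004 for Mm061 and 0.87 for Mm062. The single pools of these probes differed too, at 9.93 against 11.06 and at 10.77 against 11.75, so pool and response cannot be told apart. PXR-deficient minus CAR-deficient gave 1.53 for Mm052 (near saturation, so of uncertain size), -2.03 for Mm001 and -1.09 for Mm059. CAR/PXR-deficient minus CAR-deficient gave 0.50 for Mm062, -0.90 for Mm014 and -0.82 for Mm012. CAR/PXR-deficient minus PXR-deficient gave 2.13 for Mm001 and 1.76 for Mm024. A difference between the genotypes' single pools could enter any of these values.

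A sample lay far from its group in 3 of 56 groups of values tested, about what chance gives (1 in 20 groups). Mm014 was 0.34 in CAR-deficient replicate 1, against at most -0.07 in the others. Mm062 was -0.77 in PXR-deficient replicate 5, against -0.18 to 0.02. WT replicate 1 had 115 probes above background, against 44 to 58 on the other WT arrays.

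The negative control spots, which no comparison used, carried signal: 10.4 percent of the Lnegat1 spots and 18.1 percent of the Lnegat2 spots lay above background in at least 1 channel (15 and 26 of 144), against 0 of 480 spotting buffer spots. The signal lay on few arrays: 19 of 24 had no such Lnegat1 spot and 16 of 24 no such Lnegat2 spot. CAR/PXR-deficient arrays gave 8 of the 15 (on 3 of 6 arrays) and 12 of the 26 (on 4 of 6), PXR-deficient arrays 1 and 7, and CAR-deficient arrays 0 and 1. WT replicate 1, the array with 115 probes above background, gave 6 of the 15 and 6 of the 26, and without it the shares were 6.52 and 14.5 percent (9 and 20 of 138).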

How the results depend on the processing

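Of the 26 processing alternatives, 9 were chosen after the data were seen: saturated spots kept, spots below background left out, 24 arrays counted separately, 3 alike pairs counted once, position as a term, the upper arrays alone, the lower arrays alone, the authors' table after median centring, and leaving out WT replicates 1 and 6 together.

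Of 1089 alternative values of the 32 named probe results, 994 kept their direction and side of the threshold, 90 kept their direction but did not pass, and 5 reversed. The reversed values were Mm014 and Mm133 in the CAR/PXR-deficient response with calibration spike-in centring (0.0927 and 0.42) and in the authors' value table (0.36 and 0.80), and Mm012 in CAR/PXR-deficient minus CAR-deficient in the authors' value table (0.33). The flagged spots limit all values: 34 probes had a value in all 23 samples. Of the counts, 77 moved by over 1.5 times, as follows; the cause was not tested unless stated. Counts in the text were 20 in WT, 0 in CAR-deficient, 26 in PXR-deficient and 27 in CAR/PXR-deficient liver, and for the differences 1 (CAR minus WT), 15 (PXR minus WT), 10 (CAR/PXR minus WT), 15 (PXR minus CAR), 6 (CAR/PXR minus CAR) and 26 (CAR/PXR minus PXR), each name standing for the deficient group.

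With no background correction CAR minus WT had 0 and CAR/PXR minus CAR 11. With median centring CAR minus WT had 7, PXR minus WT 6, CAR/PXR minus WT 16 and CAR/PXR minus CAR 0. With print-tip loess CAR minus WT had 2 and CAR/PXR minus WT 5. With scale normalization between arrays the CAR-deficient response had 16, CAR minus WT 6 and PXR minus WT 5.

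Calibration spike-in centring shifted the median of the probes by -0.31 in WT, 0.67 in CAR-deficient, 0.43 in PXR-deficient and 1.14 in CAR/PXR-deficient liver, and equal spike-ins in both channels are not certain. It gave 54 in the CAR-deficient and 74 in the CAR/PXR-deficient response, 50 for CAR minus WT, 28 for PXR minus WT, 74 for CAR/PXR minus WT and 5 for PXR minus CAR. The authors' value table gave 3 in WT, 35 in CAR-deficient, 12 in PXR-deficient and 74 in CAR/PXR-deficient liver, 16 for CAR minus WT, 8 for PXR minus WT, 61 for CAR/PXR minus WT, 3 for PXR minus CAR and 17 for CAR/PXR minus CAR. After median centring of that table WT had 11, CAR-deficient liver 11, CAR minus WT 5, CAR/PXR minus WT 18 and CAR/PXR minus CAR 15.

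Among the alternatives of scaling, the share of calls that were higher moved by over 10 percentage points in these cases. With median centring it changed by -16.3 points in the CAR/PXR-deficient response and 28.6 for CAR minus WT. With print-tip loess it changed by 50 for CAR minus WT, 28.2 for PXR minus WT, 20 for CAR/PXR minus WT, 10.95 for PXR minus CAR and 26.2 for CAR/PXR minus CAR. With scale normalization it changed by 50 for CAR minus WT, -33.3 for PXR minus WT and -10.5 for CAR/PXR minus PXR. With spike-in centring it changed by -26.7 in WT, 30.5 in PXR-deficient and 51.9 in CAR/PXR-deficient liver, and by 98.0, 63.1, 57.3, 26.7, 83.3 and 45.9 for the 6 differences in the order above. In the authors' table it changed by 40.0, 30.1 and 51.9 in the same 3 responses, and by 100, 54.2, 58.4, -20, 83.3 and 49.6 for the differences. In that table after median centring it changed by 12.7 in WT, 80.0 for CAR minus WT, 26.7 for PXR minus WT, 26.7 for CAR/PXR minus WT and 23.3 for CAR/PXR minus CAR. Under the other processing alternatives it moved by over 10 points in 26 of 169 shares compared, by -33.3 to 50 points: 8 for CAR minus WT, 8 for CAR/PXR minus CAR, 6 for PXR minus WT and 1 each for WT, CAR/PXR-deficient liver, CAR/PXR minus WT and CAR/PXR minus PXR.

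With spots of poor quality kept CAR minus WT had 7, PXR minus CAR 23 and CAR/PXR minus CAR 10. CAR minus WT had 2 with spots below background left out, 2 with the median of pixels, 2 with 24 arrays counted separately and 3 without WT replicates 1 and 6 together. With the stricter filter on dim probes, which leaves 49, the CAR/PXR-deficient response had 14, CAR minus WT 0 and CAR/PXR minus CAR 0. Fitting only the groups compared gave 12 in WT, 18 in CAR-deficient and 13 in CAR/PXR-deficient liver, 2 for CAR minus WT, 4 for PXR minus WT and 4 for CAR/PXR minus WT. Array quality weights gave 13 in WT, 20 in CAR-deficient liver, 3 for CAR minus WT, 25 for PXR minus CAR and 19 for CAR/PXR minus CAR. A fold of at least 1.5, which adds a condition, gave 9 in WT, 15 in PXR-deficient and 11 in CAR/PXR-deficient liver, 9 for PXR minus WT and 5 for CAR/PXR minus WT. With 3 alike pairs counted once the PXR-deficient response had 15, CAR minus WT 2 and PXR minus WT 9.

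With replicate number as a replicate block the counts were 19, 0, 25 and 29 for the responses and 1, 13, 12, 17, 12 and 25 for the differences, of which only CAR/PXR minus CAR at 12 moved by over 1.5 times. With the replicate block Mm024 in PXR minus WT did not pass (-0.87, adjusted p = 0.264). The numbers do not pair the samples: correlations of same-numbered arrays ran from -0.52 to 0.68, and 3 of 24 arrays correlated best with their own number.

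With fewer samples, the upper arrays alone gave 13 in PXR-deficient and 13 in CAR/PXR-deficient liver, and 0, 2, 5, 5, 0 and 13 for the differences. The lower arrays alone gave 10 in WT, 14 in PXR-deficient and 4 in CAR/PXR-deficient liver, 7 for CAR minus WT, 4 for CAR/PXR minus WT, 8 for PXR minus CAR, 0 for CAR/PXR minus CAR and 12 for CAR/PXR minus PXR; WT had 1 lower array, assumed to vary like the other groups.

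With single samples left out the counts ran from 15 to 20 in WT, from 0 to 0 in CAR-deficient, from 15 to 24 in PXR-deficient and from 20 to 28 in CAR/PXR-deficient liver. They ran from 0 to 12 for CAR minus WT, 9 to 19 for PXR minus WT, 5 to 14 for CAR/PXR minus WT, 11 to 18 for PXR minus CAR, 0 to 8 for CAR/PXR minus CAR and 19 to 27 for CAR/PXR minus PXR.

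Not run, as the files give no gene names, were housekeeping centring, the mean of all probes of a gene, and the alternatives for gene lists and receptor genes; no slide, print batch or scan date is given for a block.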

Other observations

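No test here was in the plan fixed before the data were examined. The test of the interaction and the test without Mm038 and Mm039 were written before their results were seen; the test of neighbouring probes was chosen after.

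The genotypes form a 2-by-2 layout, so each probe can be tested for whether losing both receptors changed the log2 response by the sum of the 2 single losses. The threshold for the interaction was passed by 14.1 percent of the probes, 11 of 78, with 2 above and 9 below the sum. This argues against the hypothesis that CAR and PXR add to the log2 response independently, for the measured ratios only. Of 100 splits of the samples into the 4 groups, only the real one, 1, gave as many, and the highest other gave 2. These splits removed every difference between the groups, so they do not test additivity with the effects of the single losses present. They also cannot exclude a pool that stood apart, and the count was not run under the processing alternatives. Mm001 had the largest interaction among the 3 with the lowest adjusted p, at 2.32 (SE 0.49, adjusted p = 0.00279); its log2 ratio was -2.10 in PXR-deficient liver and near 0 in CAR-deficient (-0.08) and CAR/PXR-deficient (0.03) liver. Mm051 had -1.44 (SE 0.31, adjusted p = 0.00279) and Mm102 0.92 (SE 0.18, adjusted p = 0.00251). These probes were chosen after their values were seen. As each genotype had its own pool, a pool that stood apart would also appear as an interaction. Of the deviation in PXR-deficient liver, 76.8 percent lay in the pool channel for Mm001, 7.70 percent for Mm051 and 31.8 percent for Mm102.

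Probes with neighbouring ID numbers responded alike in WT. Over 44 pairs of consecutive numbers the mean absolute difference of the log2 ratio was 0.33, against 0.50 in random orders (one-sided permutation test with 10000 orders, p = 0.0078, adjusted p = 0.0331 over 8 tests). Without Mm038 and Mm039, by the same permutation test, it was 0.29 against 0.38 (p = 0.0124, adjusted p = 0.0331). In PXR-deficient liver the permutation test had 0.49 against 0.70 (p = 0.0099, adjusted p = 0.0331), and 0.45 against 0.57 without Mm038 and Mm039 (p = 0.046, adjusted p = 0.092). In CAR-deficient and CAR/PXR-deficient liver the permutation test did not pass with all probes (p = 0.249 and 0.298). A candidate explanation is that related probes have neighbouring numbers, as when members of a gene family were numbered together; the files do not give the genes, so this stays a hypothesis.

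The ratio spike-ins kept their direction with few exceptions. Relative to the calibration spots, Lratio8 was at 3.20 ± 0.33 on 23 arrays and Lratio7 at -2.90 ± 0.39 on 13. Lratio2 was above 0 on 19 of 20 arrays and Lratio6 on 19 of 21. The calibration spots themselves lay far from the probes in CAR/PXR-deficient replicates 1 and 2, where the median log2 ratio of the calibration spots was -4.93 and -5.03 and that of the probe spots -2.25 and -2.21.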
